A study of Homo sapiens with 16 samples.

How the data were processed

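HCT116 colorectal carcinoma cells of 4 lines (shNT, shTIP60, shCDK8 and HIF1A-null) were kept in normoxia (21% oxygen) or hypoxia (1% oxygen for 24 h), and poly(A) RNA of 2 independent biological replicates per combination was sequenced on an Ion Torrent Proton instrument with an Ion Total RNA-seq kit, per the labels' protocols. The deposited values were raw read counts per gene symbol, with a column for each of 16 libraries, and the authors had applied no scaling to these counts per the labels. Per the submitters' processing notes, the tools were GSNAP (2013-10-28), HTSeq (0.5.4p5), DESeq (1.14.0) and R (3.0.3) on the human build hg19. The gene annotation, the strand setting of the counting and the filters on reads were not given in the sources used here. Antisense and overlapping genes, near-identical copies such as SLC2A3 and SLC2A14, histone genes, ribosomal protein genes and small nucleolar RNAs inside host genes therefore have uncertain counts.

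The table held 23669 genes. Total counts per library ran from 26620086 to 39401494, and 16824 to 17817 genes had at least 1 count. A floor of 3 counts corresponded to 0.0716 to 0.112 CPM. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. The pairs of replicates had Pearson r of 0.987 to 0.994 across genes, which are not independent replicates, and their differences exceeded counting error, at 8.56 to 64.8 times its variance. Trimmed mean of M-values (TMM) factors were 0.862 to 0.965 in hypoxia and 1.01 to 1.12 in normoxia, and the 10 most abundant genes took 5.87 to 7.35% of counts in hypoxia and 3.50 to 3.97% in normoxia.

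Genes were tested with edgeR 4.0.16 in R 4.3.3: low counts were removed by group (at least 10 counts in enough libraries and 15 in total, leaving 15520 genes, 65.6%), a quasi-likelihood model with robust dispersion and 1 coefficient per group was fitted to all 16 libraries with TMM factors (8 residual degrees of freedom, common biological coefficient of variation 0.132), and two-sided p were adjusted by Benjamini-Hochberg at 0.05. The 13 comparisons were hypoxia against normoxia in each of 4 lines, each of 3 lines against shNT in normoxia and in hypoxia (6 comparisons), and 3 differences between the hypoxia response of a line and that of shNT. CPM were computed with TMM factors. Where a group had 0 counts, a lower bound was computed against the floor over the group, and where it had 1 to 3 counts, a ratio with its 95% counting interval is given. Coordinates of the named genes came from GENCODE release 44 lifted to GRCh37, the build of the deposited data.

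Before the data were examined, the comparisons, the tests, 31 gene lists of 717 members, the alternatives and the rule for the genes to name were fixed. The rule took the targeted genes HIF1A, CDK8 and KAT5, a panel of 12 hypoxia genes in every hypoxia comparison, the 6 genes with the highest and the 6 with the lowest fold change among those called, at 5 CPM or more in the higher group and with both libraries of a group above both of the other, and up to 4 members with the smallest adjusted p per list described. For response differences, all 4 differences between libraries had to lie above those of the other line. Genes known only by a clone or locus identifier and pseudogenes were passed over. Some genes that the rule took are not reported here, though they remain in the counts over lists and results. Of the list members, 704 were in the table. The list of mitochondrially encoded mRNAs had 0, so 30 lists were tested. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the 30 lists of a comparison, and repeated with an estimated correlation and with fry. Fry asks whether members move on balance in a direction, or in either direction in its mixed form, and compares no list with other genes. Members called are counted over all genes tested and adjusted over the list alone. How far each line kept the shNT response was measured as a slope through 0 over the core hypoxia genes, without a test across genes. Calls shared between lines were set beside 50 simulated draws in which the other groups were unchanged from shNT.

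The fit was tested on simulated counts with 200 changed genes. For the hypoxia comparison of shNT (15178 genes in that step) it recovered 26.9%, 85.1% and 98.5% of genes changed by 1.5, 2 and 4 times, with 7 of 147 calls false. For the difference of responses between HIF1A-null and shNT (15149 genes) it recovered 8.96%, 41.8% and 90.9%, with 7 of 101 calls false. A list raised by construction was called in each, and no other list was. Alternatives were DESeq2 1.42.0, size factors by relative log expression (RLE), library totals alone, other filters (no filter except 1 count, or a mean of at least 5 CPM), a fit of only the groups compared, a test against 1.5-fold (glmTreat), thinning to the total of the shallowest library, other thresholds, and the removal of each library in turn. A sign that differed between a pair of values neither of which passed the test was not counted as a change of direction. The data columns carry library numbers and no replicate numbers, so no pairing of replicates was used. The series of library numbers, the first holding library A and the second library B of every group, was added as an alternative after the column names were seen. Each group had 2 libraries, too few for other splits of the samples or for a test of outlying libraries within a group. All 16 libraries and every column were used.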

Results

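Poly(A) RNA was sequenced from HCT116 cells, an established human colorectal carcinoma line, kept at 21% oxygen (normoxia) or for 24 h at 1% oxygen (hypoxia). 4 derivatives of the line were compared: cells with a non-targeting shRNA (shNT), cells with an shRNA against TIP60, the histone acetyltransferase encoded by KAT5 (shTIP60), cells with an shRNA against CDK8, a kinase of the Mediator complex (shCDK8), and cells with HIF1A deleted (HIF1A-null). HIF1A encodes the oxygen-regulated subunit of hypoxia-inducible factor 1 (HIF1). Each of the 8 combinations of line and oxygen had 2 libraries described as independent biological replicates. The floor of 3 counts corresponded to 0.0716 to 0.112 CPM (a gene's count scaled to a common library total). Of 23669 genes, 15520 passed the filter on low counts and were tested. Levels are means in CPM ± SD over n = 2 libraries, and changes are log2 fold changes ± SE with adjusted p from edgeR's quasi-likelihood test. The comparisons asked which genes responded to hypoxia, how that response differed in lines altered at HIF1A, CDK8 or TIP60, and how the lines differed at a given oxygen level. Libraries A and B are those of the first and second series of library numbers. Each target had only a single altered line, so the libraries replicate cultures and not the knockdown or deletion. Clone, vector and off-target effects cannot be separated from loss of the target, and the labels give no shRNA for HIF1A-null.

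In shNT, HIF1A (chromosome 14, 62162231 to 62214977, 15 exons in the canonical transcript, GRCh37) was at 107.5 ± 0.805 CPM in normoxia and 65.9 ± 6.55 CPM in hypoxia, a log2 change of -0.71 ± 0.15 (adjusted p = 0.00124). HIF1A-null cells had 13.6 ± 0.763 CPM in normoxia, -2.99 ± 0.16 against shNT (adjusted p = 4.19e-09). In hypoxia the reads assigned to HIF1A in that line rose to 48.9 ± 12.4 CPM, a log2 change of 1.85 ± 0.15 (adjusted p = 4.91e-07). The remaining difference from shNT in hypoxia was -0.43 ± 0.15 (adjusted p = 0.0283), and it was lost without shNT hypoxia library B or HIF1A-null hypoxia library A (adjusted p between 0.181 and 0.317). Counts per gene do not show which HIF1A exons these reads covered. CDK8 (chromosome 13, 26828241 to 26995119, 13 exons in the canonical transcript) was lower in shCDK8 than in shNT in normoxia (log2 -2.05 ± 0.14) and in hypoxia (-2.32 ± 0.14), at 6.29 ± 0.729 against 26.0 ± 1.78 CPM and 5.64 ± 0.274 against 28.1 ± 0.280 CPM. KAT5 (chromosome 11, 65479467 to 65487075, 13 exons in the canonical transcript) was lower in shTIP60 in normoxia (-2.12 ± 0.13) and in hypoxia (-2.08 ± 0.13), at 19.7 ± 0.762 against 85.8 ± 1.34 CPM and 21.5 ± 0.703 against 90.5 ± 4.28 CPM. Adjusted p was at most 8.32e-08 in these 4 knockdown comparisons.

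**Figure D1:**
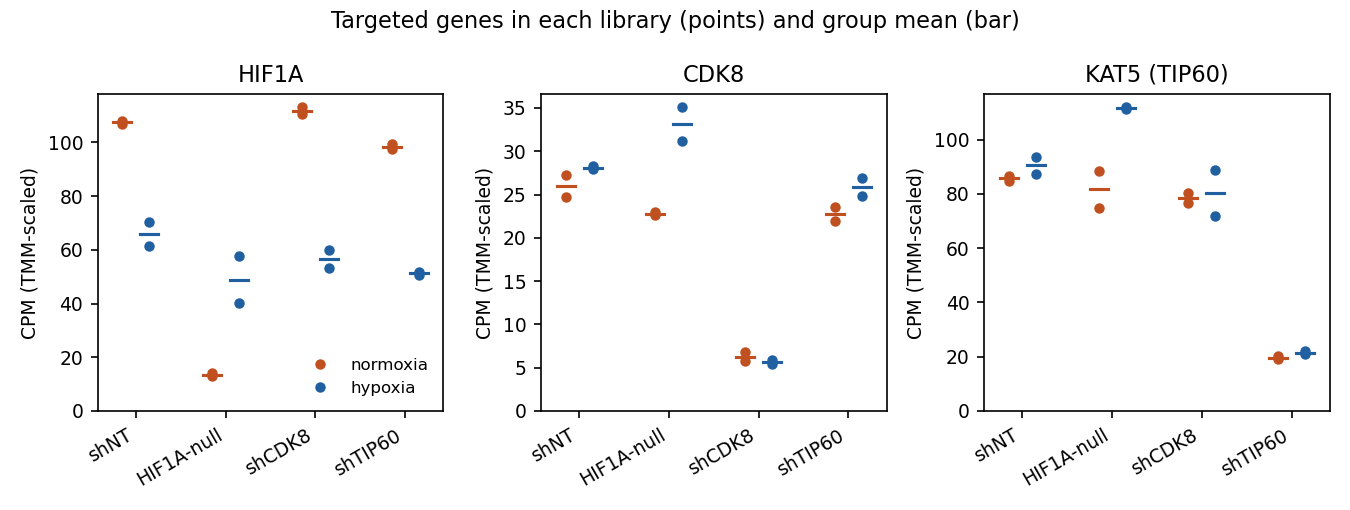
CPM of HIF1A, CDK8 and KAT5 (vertical axes, from 0) in each library (points) with the mean of 2 libraries (bars) for the 4 lines in normoxia and hypoxia. HIF1A in HIF1A-null cells went from 13.6 CPM in normoxia to 48.9 CPM in hypoxia, while CDK8 in shCDK8 and KAT5 in shTIP60 stayed low under both conditions.

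In shNT cells, hypoxia raised the classical HIF target program. ANGPTL4, a secreted inhibitor of lipoprotein lipase, rose from 8.48 ± 0.110 to 1270 ± 339 CPM, a log2 change of 7.23 ± 0.25 (adjusted p = 8.00e-11). CA9, a membrane carbonic anhydrase that exports acid, rose from 1.59 ± 0.837 to 50.1 ± 8.38 CPM (5.00 ± 0.28), and the angiogenic factor VEGFA from 68.8 ± 5.37 to 286.5 ± 4.64 CPM (2.06 ± 0.15). All 12 genes of the hypoxia panel rose, from LDHA, lactate dehydrogenase A (1.80 ± 0.15), to ANKRD37, an ankyrin repeat protein (6.44 ± 0.30). Among the largest gains were also CXCR4, the receptor of the chemokine CXCL12 (5.49 ± 0.40), DDIT4, an inhibitor of mTORC1 (5.43 ± 0.24), and SLC2A3, the glucose transporter GLUT3 (5.36 ± 0.26). ANGPTL4 lies on chromosome 19 (8428173 to 8439254), CA9 on chromosome 9 (35673925 to 35681156) and VEGFA on chromosome 6 (43737921 to 43754224). SLC2A14 (5.53 ± 0.39) is a near-identical copy of SLC2A3, so reads of this pair are uncertain. The deepest losses were in RPS6KL1 (-3.25 ± 0.38), LONRF2 (-2.97 ± 0.32), FAM111B (-2.86 ± 0.33), CHAC2, an enzyme of glutathione breakdown (-2.79 ± 0.27), CLSPN, the replication checkpoint adaptor claspin (-2.79 ± 0.29), and CCNE2, cyclin E2 (-2.78 ± 0.24).

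By gene list, 51 of 51 core hypoxia genes rose (51 adjusted over the list alone, camera adjusted p = 2.42e-39, also adjusted p = 0.00429 with an estimated correlation). Of glycolysis and lactate export genes, 22 of 25 rose and 2 fell (22 and 2 adjusted over the list alone, camera adjusted p = 3.35e-14, adjusted p = 0.0858 with an estimated correlation). PFKFB4 (3.74 ± 0.15) and ALDOC (3.41 ± 0.20), a regulator and an aldolase of glycolysis, led that list beside SLC2A3. Among immediate early and serum response genes, 24 of 28 rose and 1 fell (26 and 1 adjusted over the list alone, camera adjusted p = 6.68e-09, adjusted p = 0.0858 with an estimated correlation). DUSP1, a MAP kinase phosphatase, was at 2.88 ± 0.18. JmjC histone demethylases, which use oxygen as a substrate, were also shifted: 11 of 17 rose and 1 fell (11 and 1 adjusted over the list alone, camera adjusted p = 1.41e-04, adjusted p = 0.0858 with an estimated correlation), with KDM3A (3.31 ± 0.19) up and MINA (-1.16 ± 0.12) down. Collagen processing genes followed, where 7 of 15 rose and 1 fell (7 and 1 adjusted over the list alone, camera adjusted p = 0.00434, adjusted p = 0.0858 with an estimated correlation), led by the prolyl hydroxylase P4HA1 (3.51 ± 0.19) and the lysyl hydroxylase PLOD2 (2.71 ± 0.18). Of p53 targets, 11 of 24 rose and 3 fell (11 and 3 adjusted over the list alone, camera adjusted p = 0.0321, adjusted p = 0.259 with an estimated correlation). GDF15 (2.24 ± 0.13) rose and C12orf5, which encodes the fructose bisphosphatase TIGAR, fell (-2.44 ± 0.20).

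Other lists fell in shNT. Of DNA replication and E2F targets, 28 of 32 fell (30 adjusted over the list alone, camera adjusted p = 7.15e-13, adjusted p = 0.257 with an estimated correlation). They included CCNE1 (-1.95 ± 0.18) and the helicase subunit MCM6 (-1.68 ± 0.16). Of ribosome biogenesis genes, 20 of 27 fell and 1 rose (21 and 1 adjusted over the list alone, camera adjusted p = 5.94e-07, adjusted p = 0.320 with an estimated correlation). NIP7 (-1.74 ± 0.13) and PNO1 (-1.43 ± 0.15) had the smallest p. 13 of 17 cytosolic heat shock genes fell (13 adjusted over the list alone, camera adjusted p = 8.56e-06, adjusted p = 0.108 with an estimated correlation). They included the cochaperone DNAJA1 (-1.73 ± 0.14) and HSPH1 (-2.04 ± 0.23). Of nuclear-encoded oxidative phosphorylation genes, 14 of 38 fell and 1 rose (13 and 1 adjusted over the list alone, camera adjusted p = 0.00604, adjusted p = 0.499 with an estimated correlation). Cytochrome c, CYCS, was at -1.44 ± 0.15. In contrast, of cytoplasmic ribosomal protein genes, 16 of 36 rose (16 adjusted over the list alone, camera adjusted p = 3.48e-04, adjusted p = 0.547 with an estimated correlation), and reads of these genes can be shared with processed pseudogenes. Removal of 1 library took the members called down to 7 (oxidative phosphorylation, without shNT normoxia library A) and 5 (ribosomal proteins, without shNT hypoxia library B). In all, 6311 of 15520 genes changed, 3208 up and 3103 down, and 1962 differed by more than 1.5-fold in a test against that bound. With library totals in place of TMM the split was 2116 up and 4605 down, since that scaling moved the median of all genes by -0.20, and without shNT normoxia library A the count was 4104.

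In shTIP60 cells the same panel rose in full, from LDHA (1.79 ± 0.15) to ANKRD37 (5.66 ± 0.30), with ANGPTL4 (6.28 ± 0.24), the stress gene NDRG1 (4.58 ± 0.27), DDIT4 (4.48 ± 0.22) and the vasodilator peptide gene ADM (4.36 ± 0.20) at the top. CA9 went from 1.84 ± 0.122 to 31.0 ± 2.37 CPM and VEGFA from 57.5 ± 3.64 to 442.5 ± 58.6 CPM. SNAR-E, a small noncoding RNA with near-identical copies whose counts are uncertain (-2.97 ± 0.43), FAM111B (-2.69 ± 0.33), RPS6KL1 (-2.63 ± 0.33) and CHAC2 (-2.60 ± 0.26) fell most. Of the core hypoxia genes, 50 of 51 rose (50 adjusted over the list alone, camera adjusted p = 4.40e-41, also adjusted p = 0.00368 with an estimated correlation). Of glycolysis genes, 22 of 25 rose and 1 fell (22 and 1 adjusted over the list alone, camera adjusted p = 1.63e-16, adjusted p = 0.0725 with an estimated correlation). In DNA replication, 30 of 32 fell (31 adjusted over the list alone, camera adjusted p = 3.20e-13, adjusted p = 0.228 with an estimated correlation). GINS3 was at -2.44 ± 0.23. In mitosis, 15 of 28 fell and 1 rose (16 and 1 adjusted over the list alone, camera adjusted p = 1.13e-04, adjusted p = 0.369 with an estimated correlation). Cyclin B1, CCNB1, was at -1.12 ± 0.14 and KIF11 at -0.86 ± 0.16. Cholesterol synthesis genes moved up, where 15 of 24 rose and 1 fell (15 and 2 adjusted over the list alone, camera adjusted p = 3.21e-04, adjusted p = 0.228 with an estimated correlation). INSIG1, a sterol-regulated retention factor, was at 2.56 ± 0.21. 11 of 18 endoplasmic reticulum chaperone genes rose and 1 fell (13 and 1 adjusted over the list alone, camera adjusted p = 5.07e-04, adjusted p = 0.248 with an estimated correlation). The chaperone HSPA5 was at 1.34 ± 0.21.

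Of angiogenic and vasoactive factors in shTIP60, 9 of 14 rose and 2 fell (9 and 2 adjusted over the list alone, camera adjusted p = 1.24e-04, adjusted p = 0.0725 with an estimated correlation). Among NF-kB and inflammatory genes, 6 of 16 rose (6 adjusted over the list alone, camera adjusted p = 0.0130, adjusted p = 0.270 with an estimated correlation). They included NFKB2 (1.67 ± 0.15) and BIRC3 (1.96 ± 0.24). Epithelial and colon carcinoma markers were up as well, where 6 of 17 rose and 2 fell (6 and 2 adjusted over the list alone, camera adjusted p = 0.0264, adjusted p = 0.369 with an estimated correlation). E-cadherin, CDH1, was at 1.94 ± 0.18. Of mesenchymal and fibroblast markers, 4 of 14 rose (4 adjusted over the list alone, camera adjusted p = 0.0174, adjusted p = 0.228 with an estimated correlation). TAGLN, a smooth muscle actin-binding protein, was at 1.22 ± 0.24. ACTA2 lost its call without shTIP60 normoxia library A and VIM without shTIP60 hypoxia library B (adjusted p = 0.0605 and 0.0895), and edgeR called 4 members of that list with hypoxia in shNT, 4 in HIF1A-null and 5 in shCDK8. Ribosome biogenesis was lower, where 20 of 27 fell and 1 rose (20 and 1 adjusted over the list alone, camera adjusted p = 4.92e-06, adjusted p = 0.294 with an estimated correlation). NIP7 was at -1.45 ± 0.13. Fewer members were called with a library removed, 5 (mitosis, without shTIP60 normoxia library A or shTIP60 hypoxia library B) and 3 (NF-kB, without shTIP60 normoxia library A or shTIP60 hypoxia library B). A total of 6083 genes changed with hypoxia in shTIP60, 3007 up and 3076 down, and 1726 passed the test against 1.5-fold. Library totals gave 1899 up and 4859 down (median of all genes -0.23), and the count was 3786 without shTIP60 normoxia library A and 3877 without shTIP60 hypoxia library A.

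In shCDK8 cells hypoxia again raised all 12 panel genes, from LDHA (1.62 ± 0.15) to CA9 (5.69 ± 0.41). CA9 started at 0.124 ± 0.0743 CPM in this line and reached 6.86 ± 0.681 CPM. ANGPTL4 (5.53 ± 0.23), ANKRD37 (4.93 ± 0.30), DDIT4 (4.43 ± 0.22), NDRG1 (4.24 ± 0.27) and SLC2A3 (4.15 ± 0.25) were the other strongest gains. GPR15, a chemoattractant receptor (-2.49 ± 0.42), KRT20, the intestinal keratin 20 (-2.44 ± 0.37), the interferon-stimulated gene IFIT1 (-1.83 ± 0.31) and FAM222A (-1.81 ± 0.27) fell most among genes with unambiguous reads. Core hypoxia genes moved as a block: 51 of 51 rose (51 adjusted over the list alone, camera adjusted p = 2.85e-50, also adjusted p = 0.00179 with an estimated correlation). For glycolysis, 22 of 25 rose and 2 fell (22 and 2 adjusted over the list alone, camera adjusted p = 3.29e-18, adjusted p = 0.0670 with an estimated correlation). For immediate early genes, 22 of 28 rose and 1 fell (26 and 1 adjusted over the list alone, camera adjusted p = 5.62e-10, adjusted p = 0.0676 with an estimated correlation). Of DNA replication genes, 15 of 32 fell (17 adjusted over the list alone, camera adjusted p = 4.43e-06, adjusted p = 0.436 with an estimated correlation). CCNE2 was at -1.22 ± 0.21 and POLE2 at -0.97 ± 0.19. Ribosome biogenesis was lower, where 17 of 27 fell (18 adjusted over the list alone, camera adjusted p = 2.71e-07, adjusted p = 0.328 with an estimated correlation). NIP7 was at -1.22 ± 0.12. 11 of 17 heat shock genes fell (11 adjusted over the list alone, camera adjusted p = 2.49e-04, adjusted p = 0.196 with an estimated correlation). DNAJA1 was at -1.15 ± 0.14. Epithelial markers were mixed but up on balance, where 8 of 17 rose and 2 fell (9 and 2 adjusted over the list alone, camera adjusted p = 0.00328, adjusted p = 0.328 with an estimated correlation), as CDH1 (1.88 ± 0.18) and ELF3 (2.08 ± 0.18) rose against KRT20. Glycogen metabolism had 5 of 10 that rose (5 and 1 adjusted over the list alone, camera adjusted p = 0.0115, adjusted p = 0.104 with an estimated correlation). The branching enzyme GBE1 was at 1.99 ± 0.13 and the glycogen synthase GYS1 at 1.55 ± 0.16. Fewer members of the DNA replication, ribosome biogenesis, immediate early and heat shock lists were called whichever library of this line was removed. The drop was deepest without shCDK8 hypoxia library A for DNA replication and without shCDK8 hypoxia library B for the others. Each removal leaves a group with a lone library. Hypoxia changed 3848 genes in shCDK8, 2135 up and 1713 down, 589 of them (475 up) by the test against 1.5-fold. The split was 1447 up and 3085 down with library totals (median of all genes -0.16), and the count was 2115 without shCDK8 normoxia library B, 2502 without shCDK8 hypoxia library A and 1846 without shCDK8 hypoxia library B.

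In HIF1A-null cells under hypoxia, the glucocorticoid-induced leucine zipper gene TSC22D3 (4.83 ± 0.26), the stress transcription factor DDIT3, also called CHOP (4.83 ± 0.32), the nuclear receptor NR4A3 (4.78 ± 0.33), the sterol regulator INSIG1 (4.24 ± 0.23) and the reticulum-associated degradation gene HERPUD1 (4.07 ± 0.25) rose most. HIST2H2BE, a histone gene with near-identical copies whose reads are uncertain, rose as well (4.09 ± 0.53). GPR15 (-5.58 ± 0.50), C14orf169, a JmjC hydroxylase gene (-4.57 ± 0.28), MYBPH, a myosin-binding protein gene (-4.24 ± 0.24), SNAR-E with its near-identical copies (-4.05 ± 0.44), LCMT2 (-3.71 ± 0.40) and TIGD5 (-3.47 ± 0.43) fell most. C14orf169, LCMT2 and TIGD5 are intronless, and 271 single-exon genes had a median of -0.44 in this comparison. Of the hypoxia panel, ANKRD37 (3.75 ± 0.33), ADM (3.37 ± 0.19), NDRG1 (2.67 ± 0.25), VEGFA (1.86 ± 0.15), KDM3A (1.66 ± 0.18), P4HA1 (1.55 ± 0.18) and PDK1 (1.25 ± 0.19) rose. LDHA rose by 0.48 ± 0.15 (adjusted p = 0.0180), a call lost without HIF1A-null normoxia library A or hypoxia library B (adjusted p between 0.103 and 0.143). BNIP3, a mitophagy receptor (-0.02 ± 0.16, adjusted p = 0.918), and SLC2A1, the glucose transporter GLUT1 (0.24 ± 0.17, adjusted p = 0.277), did not pass the test, although SLC2A1 passed without HIF1A-null hypoxia library B (adjusted p = 0.0414). EGLN3, a HIF prolyl hydroxylase, fell (-1.26 ± 0.21). CA9 had 2 reads over both normoxia libraries and 15 over both hypoxia libraries, a ratio of 10.3 (95% counting interval 2.40 to 93.2). Its call ended without either normoxia library or without hypoxia library B (adjusted p from 0.0520 to 0.117).

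Cholesterol synthesis rose broadly in HIF1A-null cells, where 19 of 24 rose and 2 fell (20 and 2 adjusted over the list alone, camera adjusted p = 7.61e-11, adjusted p = 0.0726 with an estimated correlation). HMGCS1, a synthase of the early pathway, was at 2.96 ± 0.18. In the amino acid stress response, 18 of 23 rose and 1 fell (19 and 1 adjusted over the list alone, camera adjusted p = 8.57e-10, adjusted p = 0.0726 with an estimated correlation). Among endoplasmic reticulum chaperones, 17 of 18 rose (17 adjusted over the list alone, camera adjusted p = 2.26e-09, adjusted p = 0.0726 with an estimated correlation). HSPA5 was at 3.21 ± 0.22 and HYOU1 at 1.34 ± 0.15. Of NRF2 targets, 8 of 21 rose (11 adjusted over the list alone, camera adjusted p = 4.76e-04, adjusted p = 0.0726 with an estimated correlation). The cystine transporter SLC7A11 was at 2.42 ± 0.25. Core hypoxia genes responded in part, where 29 of 51 rose and 3 fell (31 and 4 adjusted over the list alone, camera adjusted p = 2.26e-09, adjusted p = 0.0726 with an estimated correlation), and glycolysis genes likewise, where 14 of 25 rose (15 and 1 adjusted over the list alone, camera adjusted p = 2.79e-05, adjusted p = 0.238 with an estimated correlation). For immediate early genes, 20 of 28 rose and 1 fell (22 and 1 adjusted over the list alone, camera adjusted p = 2.26e-09, adjusted p = 0.0726 with an estimated correlation), led by ATF3 (3.54 ± 0.21) and NR4A1 (3.32 ± 0.19). Of mitophagy and HIF-linked cell death genes, 7 of 11 rose (7 adjusted over the list alone, camera adjusted p = 0.00278, adjusted p = 0.209 with an estimated correlation). DNA replication was lower, where 17 of 32 fell and 2 rose (17 and 2 adjusted over the list alone, camera adjusted p = 0.00513, adjusted p = 0.720 with an estimated correlation). GINS3 was at -1.41 ± 0.22. In the interferon-stimulated list, 13 of 34 fell and 3 rose (13 and 3 adjusted over the list alone, camera adjusted p = 0.0248, adjusted p = 0.689 with an estimated correlation). CMPK2 was at -2.29 ± 0.32. The call of this list was not made with library totals alone.

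Members called were down to 7 (DNA replication, without HIF1A-null normoxia library A) and 7 (interferon-stimulated, without HIF1A-null hypoxia library B) with a library removed. Hypoxia changed 5893 genes in HIF1A-null cells, 2935 up and 2958 down, and 1895 exceeded 1.5-fold by the test against that bound. The count was 3442 when only the 4 libraries of this line were fitted, and library totals gave 1485 up and 5141 down, with the median of all genes at -0.28.

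Whether the lines responded differently from shNT was tested on the responses themselves. In HIF1A-null cells the responses of CXCR4 (-6.55 ± 0.66), C4orf47 (-4.97 ± 0.57), EGLN3 (-4.30 ± 0.29) and PFKFB4 (-3.88 ± 0.19) were lower than in shNT, as differences of log2 fold changes. GPR110, an adhesion receptor gene without a read in HIF1A-null hypoxia (-2.77 or lower against the floor), and the antisense transcript FAM13A-AS1 (-4.13 ± 0.45), which reads without a stated strand setting cannot separate from FAM13A, were lower too. 9 of the 12 panel genes responded less, from LDHA (-1.32 ± 0.21) to EGLN3, while VEGFA (-0.20 ± 0.20, adjusted p = 0.545), ADM (-0.12 ± 0.25, adjusted p = 0.786) and CA9 (-1.81 ± 1.55, adjusted p = 0.460) did not pass the test of the difference. Responses that were higher in HIF1A-null cells included HMGCS1 (3.65 ± 0.25) and the small nucleolar RNAs SNORD33 (3.41 ± 0.74) and SNORD77 (3.33 ± 0.62), whose reads overlap their host genes and are uncertain. Histone genes HIST1H2AC (3.37 ± 0.60), HIST1H2BJ (4.16 ± 1.08) and HIST2H2BE (3.26 ± 0.80) were higher as well, with reads that near-identical copies can share. The calls of HIST1H2BJ and HIST2H2BE ended without HIF1A-null hypoxia library B or shNT normoxia library B, and that of HIST1H2BJ also without HIF1A-null normoxia library B or shNT hypoxia library A (adjusted p from 0.053 to 0.131). MYBPH (-3.92 ± 0.81) lost its call without shNT hypoxia library A (adjusted p = 0.477).

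By list, 44 of 51 core hypoxia genes responded less in HIF1A-null cells (45 adjusted over the list alone, camera adjusted p = 1.17e-33, also adjusted p = 0.00736 with an estimated correlation). 18 of 25 glycolysis genes responded less and 1 more (22 and 2 adjusted over the list alone, camera adjusted p = 1.21e-11, adjusted p = 0.0595 with an estimated correlation). 19 of 24 cholesterol synthesis genes responded more (21 and 1 adjusted over the list alone, camera adjusted p = 3.38e-15, also adjusted p = 0.0393 with an estimated correlation). IDI1 was at 2.61 ± 0.21. In the TCA cycle, 6 of 19 responded more (9 adjusted over the list alone, camera adjusted p = 3.67e-05, also adjusted p = 0.0300 with an estimated correlation). SUCLA2 was at 0.91 ± 0.19. Of DNA replication genes, 19 of 32 responded more (21 adjusted over the list alone, camera adjusted p = 3.62e-10, adjusted p = 0.309 with an estimated correlation). CCNE2 was at 1.67 ± 0.32. Of heat shock genes, 13 of 17 responded more (14 adjusted over the list alone, camera adjusted p = 6.71e-09, adjusted p = 0.0526 with an estimated correlation). HSPH1 was at 2.66 ± 0.31. For the amino acid stress response, 15 of 23 responded more and 1 responded less (15 and 1 adjusted over the list alone, camera adjusted p = 1.40e-08, adjusted p = 0.0526 with an estimated correlation). PSAT1 was at 2.34 ± 0.22. For endoplasmic reticulum chaperones, 10 of 18 responded more (10 adjusted over the list alone, camera adjusted p = 3.05e-07, adjusted p = 0.108 with an estimated correlation). HERPUD1 was at 2.46 ± 0.32. NRF2 targets had 6 of 21 responding more (6 adjusted over the list alone, camera adjusted p = 0.00560, adjusted p = 0.0526 with an estimated correlation). GCLC was at 1.07 ± 0.18. Of these lists, the members called went down to 8 (DNA replication, without shNT normoxia library A), 2 (TCA cycle, without shNT normoxia library A), 6 (reticulum chaperones, without shNT normoxia library A or HIF1A-null hypoxia library B) and 2 (NRF2 targets, without shNT normoxia library A).

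The responses of 2553 genes differed between HIF1A-null and shNT cells, 1169 higher and 1384 lower in HIF1A-null, 580 (191 higher) by the test against 1.5-fold. Library totals gave 924 higher and 1534 lower. The count was 1030 when only these 2 lines were fitted. It was 1179 without shNT normoxia library A, 1640 without HIF1A-null normoxia library B and 1524 without HIF1A-null hypoxia library B.

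The responses of shCDK8 cells differed from those of shNT at 6 of 15520 genes (532 with the library series as a term). DUSP1, the MAP kinase phosphatase, rose by 2.88 in shNT and by 0.66 in shCDK8, a difference of -2.23 ± 0.24 (adjusted p = 0.00147). TFRC, the transferrin receptor, had a higher response (1.77 ± 0.22, adjusted p = 0.00467), which was lost without shCDK8 hypoxia library A (adjusted p = 0.0511). ANGPTL4 (-1.70 ± 0.28), HOXA4 (-2.06 ± 0.32), the decoy death receptor gene TNFRSF10D (-1.64 ± 0.27) and HPCAL1 (-1.33 ± 0.18) had lower responses, each lost without shNT normoxia library A or B or shCDK8 hypoxia library A. TNFRSF10D, ANGPTL4 and HOXA4 were also lost without shCDK8 normoxia library A, TNFRSF10D and ANGPTL4 without shCDK8 normoxia library B, ANGPTL4 and HOXA4 without shCDK8 hypoxia library B or shNT hypoxia library A, and TNFRSF10D and HOXA4 without shNT hypoxia library B (adjusted p from 0.0505 to 0.253). None of the 12 panel genes differed by edgeR's test, with CA9 at 0.69 ± 0.60 (adjusted p = 0.704) and ANKRD37 at -1.51 ± 0.40 (adjusted p = 0.162). For the DNA replication list edgeR called 0 of 32 members over all genes, with 24 at an unadjusted p under 0.05 and 8 by DESeq2, and 21 responded more when adjusted over the list alone (median difference 0.82, camera adjusted p = 8.42e-16, adjusted p = 0.366 with an estimated correlation). Of core hypoxia genes, 1 of 51 responded less (10 adjusted over the list alone, camera adjusted p = 4.32e-07, adjusted p = 0.366 with an estimated correlation). The shCDK8 count was 215 by DESeq2, 384 with no filter on low counts and 1 in the test against 1.5-fold. Without shNT normoxia library A or B it was 2, without shCDK8 hypoxia library A it was 1, and without shNT hypoxia library A it was 12.

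In shTIP60 cells 5 of 15520 genes responded differently from shNT (72 with the library series as a term). IGFBP3, which encodes a binding protein of insulin-like growth factors, rose by 4.53 in shNT and 1.30 in shTIP60, a difference of -3.23 ± 0.36 (adjusted p = 0.00184). In shTIP60 its rise started from a level already far above shNT in normoxia, so the smaller rise does not mean a lower level in hypoxia. SLC2A3 rose by 5.36 and 2.69, a difference of -2.67 ± 0.31 (adjusted p = 0.00184), with the reservation about SLC2A14. PAG1 had a lower response (-2.46 ± 0.34, adjusted p = 0.0108) and HMOX1, heme oxygenase 1, a higher one (1.37 ± 0.20, adjusted p = 0.0185). ZNF608 (-1.79 ± 0.28, adjusted p = 0.0298) completed the list, was named only after its values were seen, and lost its call without any library of the 2 lines (adjusted p from 0.0687 to 0.262). PAG1 was lost without shNT normoxia library B, shTIP60 normoxia library A or either shTIP60 hypoxia library. HMOX1 was lost without any normoxia library of the 2 lines, shNT hypoxia library B or shTIP60 hypoxia library B (adjusted p from 0.0798 to 0.211). Among the 12 panel genes the smallest adjusted p of a difference from shNT was that of VEGFA (0.89 ± 0.20, adjusted p = 0.183). For cholesterol synthesis edgeR called 0 of 24 members over all genes, with 14 at an unadjusted p under 0.05 and 6 by DESeq2, and 11 responded more when adjusted over the list alone (median difference 0.69, camera adjusted p = 1.10e-16, adjusted p = 0.0854 with an estimated correlation). The shTIP60 count was 59 by DESeq2, 106 with no filter, 51 with only these 2 lines fitted and 3 against 1.5-fold. It was 2 without shNT normoxia library B, shTIP60 normoxia library A or shTIP60 hypoxia library B. It was 3 without shNT normoxia library A, shTIP60 normoxia library B or shTIP60 hypoxia library A, and 10 without shNT hypoxia library A.

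Over the 51 core hypoxia genes, the slope of each line's response against that of shNT was 0.434 in HIF1A-null, 0.857 in shCDK8 and 0.916 in shTIP60, with leave-one-library-out ranges of 0.407 to 0.452, 0.813 to 0.893 and 0.892 to 0.933. Within the first and the second library series the slopes were 0.427 and 0.411 for HIF1A-null, 0.835 and 0.863 for shCDK8, and 0.945 and 0.889 for shTIP60.

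**Figure D2:**
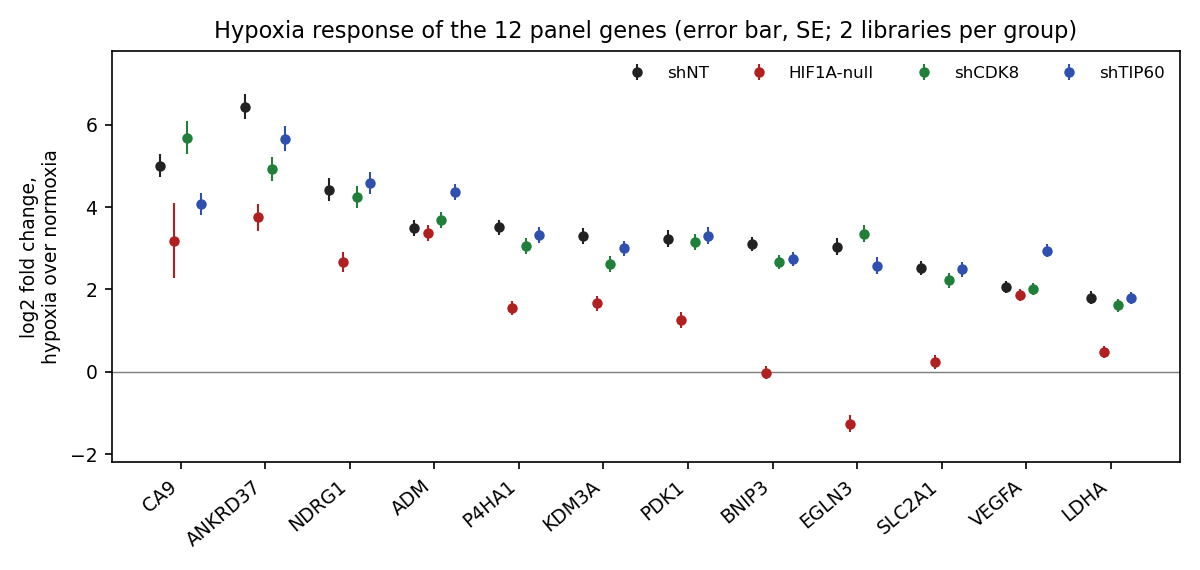
Log2 fold change of hypoxia over normoxia (vertical axis) of the 12 panel genes (horizontal axis) in the 4 lines. Points are edgeR estimates with 2 libraries per group, and bars are 1 SE from the fit to all 16 libraries. The HIF1A-null points lie at -0.02 for BNIP3 and -1.26 for EGLN3, where shNT lies at 3.11 and 3.04.

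**Figure D3:**
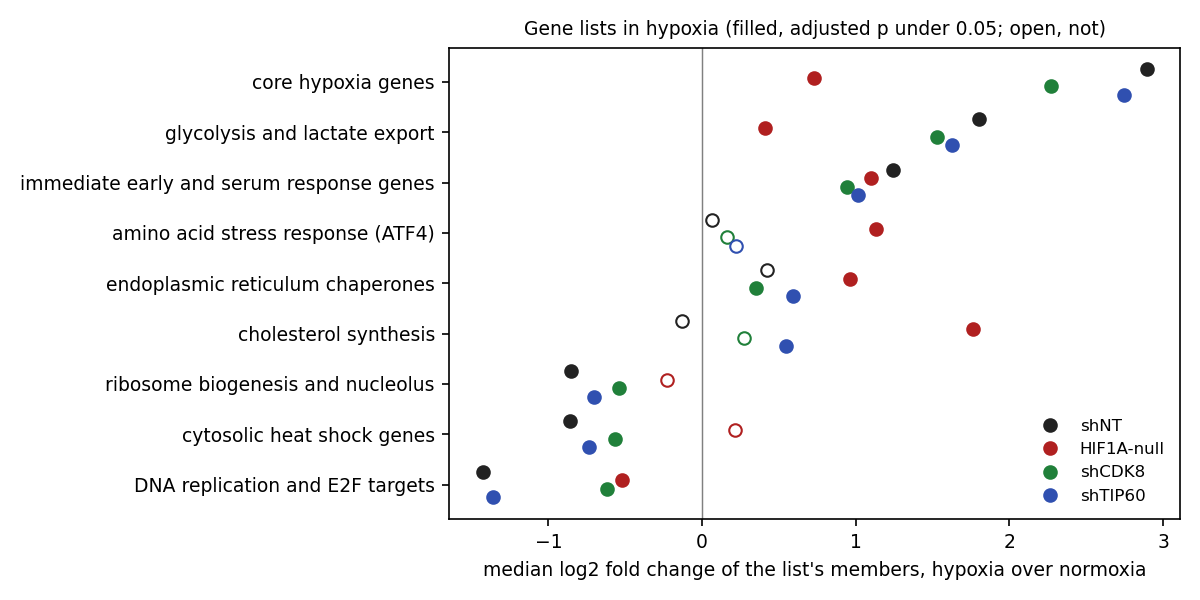
Median log2 fold change of hypoxia over normoxia (horizontal axis) over the members of 9 gene lists (vertical axis) in the 4 lines, filled where camera's adjusted p with the preset correlation was under 0.05 and open where it was not. Core hypoxia genes had medians of 2.89 in shNT and 0.73 in HIF1A-null, and cholesterol synthesis -0.13 and 1.76.

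In normoxia, the genes highest in HIF1A-null cells against shNT included MYBPH, at 48.6 ± 0.825 CPM against 0.145 ± 0.0311 (8.33 ± 0.33), and TENM3, a teneurin adhesion protein, at 46.7 ± 5.49 against 0.278 ± 0.0453 CPM (7.35 ± 0.24). GPR15 (7.49 ± 0.58), CHI3L1, a secreted chitinase-like protein (6.78 ± 0.53), ELMO1 (6.71 ± 0.65) and the epithelial transcription factor GRHL3 (6.14 ± 0.52) were also higher. SAMD3 (-7.56 ± 0.42), GPR110 (-6.92 ± 0.23), the glutamate receptor subunit GRIN2B (-6.88 ± 0.34), SNTB1 (-6.26 ± 0.30) and the growth factor FGF9 (-6.25 ± 0.47) were lower, as was LINC00326 (-5.86 ± 0.40). Of interferon-stimulated genes, 8 of 34 were higher and 2 lower (13 and 2 adjusted over the list alone, camera adjusted p = 0.0207, adjusted p = 0.794 with an estimated correlation). They included OASL (1.96 ± 0.30) and ISG15 (1.63 ± 0.26) up and IFITM2 (-1.38 ± 0.18) down. For p53 targets, 6 of 24 were higher (8 and 1 adjusted over the list alone, camera adjusted p = 0.00642, adjusted p = 0.686 with an estimated correlation). They included GDF15 (1.22 ± 0.13) and the cell cycle inhibitor CDKN1A (0.79 ± 0.12). Among immediate early genes, 8 of 28 were higher and 3 lower (11 and 4 adjusted over the list alone, camera adjusted p = 0.0409, adjusted p = 0.794 with an estimated correlation). KLF4 was at 1.70 ± 0.16. Epithelial markers had 4 of 17 higher and 2 lower (4 and 2 adjusted over the list alone, camera adjusted p = 0.0455, adjusted p = 0.794 with an estimated correlation). KRT20 was at 4.16 ± 0.36. Of oxygen sensing genes and HIF subunits, 2 of 13 were lower (2 adjusted over the list alone, camera adjusted p = 0.0440, adjusted p = 0.686 with an estimated correlation). They were HIF1A, the gene targeted in this line, and EPAS1, which lost its call without shNT normoxia library B (adjusted p = 0.0604), and the list was not called without HIF1A (camera adjusted p = 0.240). The immediate early count was 4 without shNT normoxia library A. In normoxia 1819 genes differed between HIF1A-null and shNT, 910 higher and 909 lower, 568 by the test against 1.5-fold and 1026 with only these groups fitted. The split was 776 higher and 1126 lower with library totals. Without shNT normoxia library A or B the count was 1069 or 1046.

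Between shCDK8 and shNT in normoxia, the p53 target CDKN1A was at 620.7 ± 52.8 against 188.2 ± 1.53 CPM (1.72 ± 0.12, adjusted p = 1.24e-07) and PLK2, another p53 target, was higher by 1.92 ± 0.17. TM4SF18 (6.40 ± 0.35), GPR15 (5.99 ± 0.60), the actin-like gene ACTL8 (5.80 ± 0.45), the cytokine genes TGFB2 (5.44 ± 0.39) and TNFSF4 (4.86 ± 0.28) and the collagen gene COL17A1 (4.87 ± 0.41) were higher in shCDK8. ZNF614, a zinc finger gene, had 386 reads in shNT and 0 in shCDK8, at least 107-fold lower against a floor of 3 counts over the group, and ZFP30, another, was lower with a ratio of 167 (95% counting interval 45.9 to 1382). Coagulation factor F10 (-7.57 ± 0.39), the complement inhibitor SERPING1 (-6.29 ± 0.57), CYTH4 (-5.88 ± 0.33) and the cytochrome P450 gene CYP4F11 (-5.60 ± 0.23) were lower. In the p53 list, 16 of 24 were higher and 1 lower (20 and 1 adjusted over the list alone, camera adjusted p = 9.48e-11, also adjusted p = 0.0228 with an estimated correlation). Cholesterol synthesis was lower, where 11 of 24 were lower (13 adjusted over the list alone, camera adjusted p = 4.60e-07, adjusted p = 0.407 with an estimated correlation). HMGCS1 was at -1.13 ± 0.17. Heat shock genes had 3 of 17 higher (3 adjusted over the list alone, camera adjusted p = 0.0343, adjusted p = 0.894 with an estimated correlation). DNAJA1 was at 0.68 ± 0.13. Some list counts went down to 10 (p53 targets, without shNT normoxia library A), 6 (cholesterol synthesis, without shNT normoxia library A) and 1 (heat shock, without shNT normoxia library A or shNT normoxia library B or shCDK8 normoxia library B). A total of 2028 genes differed, 900 higher and 1128 lower in shCDK8, 632 against the 1.5-fold bound. The count was 1287 without shNT normoxia library A, 1066 without shNT normoxia library B and 1262 without shCDK8 normoxia library B.

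In shTIP60 cells in normoxia, the connexin gene GJA1 had 6883 reads over 2 libraries against 1 in shNT, a ratio of 7536 (95% counting interval 1352 to 297693). The integrin gene ITGAD had 739 against 1, a ratio of 809 (95% counting interval 145 to 32000.2). IGFBP3 was at 604.1 ± 19.3 CPM (8.64 ± 0.33 against shNT), and the transcription factor TCF21 (7.64 ± 0.34), the alkaline phosphatase ALPP, with reads that its near-identical copy ALPPL2 can share (7.53 ± 0.44), and endothelin 1, EDN1 (6.63 ± 0.44), were higher. RNF43, an E3 ligase that dampens Wnt signalling, was at 1.34 ± 0.114 against 143 ± 20.5 CPM (-6.73 ± 0.24), and the transcription factor NFIB (-4.77 ± 0.33), the glutamate transporter SLC1A3 (-4.50 ± 0.32), VSNL1 (-4.27 ± 0.37), PDE4B (-3.75 ± 0.17) and GRB14 (-3.70 ± 0.29) were lower. Of interferon-stimulated genes, 20 of 34 were higher (22 adjusted over the list alone, camera adjusted p = 2.19e-07, adjusted p = 0.311 with an estimated correlation). They included OASL (2.83 ± 0.30) and ISG20 (1.87 ± 0.22). Of cholesterol synthesis genes, 18 of 24 were lower (21 adjusted over the list alone, camera adjusted p = 1.23e-09, adjusted p = 0.0947 with an estimated correlation). The sterol-sensing transcription factor SREBF2 was at -1.34 ± 0.14 and FDFT1 at -1.14 ± 0.16. NRF2 targets had 12 of 21 higher and 1 lower (13 and 2 adjusted over the list alone, camera adjusted p = 2.46e-04, adjusted p = 0.0606 with an estimated correlation). HMOX1 was at 1.45 ± 0.14. In collagen processing, 7 of 15 were higher (8 adjusted over the list alone, camera adjusted p = 0.00113, adjusted p = 0.0947 with an estimated correlation). COL4A1 was at 3.95 ± 0.46. 4 of 28 mitosis genes were lower (2 adjusted over the list alone, camera adjusted p = 2.40e-04, adjusted p = 0.666 with an estimated correlation). In this comparison the list counts went down to 8 (interferon-stimulated, without shNT normoxia library A), 10 (cholesterol synthesis, without shTIP60 normoxia library A or shTIP60 normoxia library B), 7 (NRF2 targets, without shTIP60 normoxia library B), 3 (collagen processing, without shNT normoxia library A) and 0 (mitosis, without shNT normoxia library A or shTIP60 normoxia library A or shTIP60 normoxia library B). In shTIP60 2857 genes differed from shNT in normoxia, 1595 higher and 1262 lower, 835 (592 higher) against 1.5-fold and 4830 with only these groups fitted. Without shNT normoxia libraries A or B the counts were 1431 and 1668, and without shTIP60 normoxia libraries A or B they were 1368 and 1589.

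Under hypoxia, HIF1A-null cells had 0.255 ± 0.0981 CPM of CA9 against 50.1 ± 8.38 in shNT (-7.57 ± 0.35, adjusted p = 4.85e-10). EGLN3 (-4.25 ± 0.22), ANKRD37 (-4.49 ± 0.27), BNIP3 (-2.97 ± 0.17), PDK1, the pyruvate dehydrogenase kinase (-2.41 ± 0.19), and P4HA1 (-2.04 ± 0.18) were lower as well. VEGFA was lower (-0.55 ± 0.14), SLC2A1 did not pass the test (-0.43 ± 0.17, adjusted p = 0.0517, but between 0.00421 and 0.0390 without shNT hypoxia library B or HIF1A-null hypoxia library A), and ADM (-0.55 ± 0.17, adjusted p = 0.0180) lost its call without the same libraries (adjusted p between 0.175 and 0.179). GPR110 had 2592 reads in shNT and 0 in HIF1A-null, at least 842-fold lower against the floor of 3 counts over the group, and SNTB1 was lower with a ratio of 333 (95% counting interval 114 to 1617). IGFBP3 (-6.79 ± 0.37), GRIN2B (-6.43 ± 0.33) and the protease inhibitor SERPINA1 (-6.32 ± 0.35) were lower. ASB10 was at least 117-fold higher by the same floor, with 341 reads against 0, and TENM3 (8.76 ± 0.28), the annexin ANXA10 (7.70 ± 0.30), C21orf56 (5.83 ± 0.26), GRHL3 (5.65 ± 0.63) and KRT20 (5.45 ± 0.44) were higher.

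Of the core hypoxia list, 47 of 51 were lower (48 adjusted over the list alone, camera adjusted p = 1.08e-25, also adjusted p = 0.0182 with an estimated correlation) in HIF1A-null cells, and of glycolysis genes, 20 of 25 were lower and 1 higher (21 and 1 adjusted over the list alone, camera adjusted p = 2.75e-08, adjusted p = 0.118 with an estimated correlation). PFKFB4 was at -4.00 ± 0.15 and phosphoglycerate kinase PGK1 at -2.05 ± 0.16. Collagen processing had 8 of 15 lower and 2 higher (8 and 2 adjusted over the list alone, camera adjusted p = 0.00504, adjusted p = 0.0950 with an estimated correlation). PLOD2 was at -3.33 ± 0.19. 20 of 24 cholesterol synthesis genes were higher (22 adjusted over the list alone, camera adjusted p = 2.02e-10, adjusted p = 0.0744 with an estimated correlation). HMGCS1 was at 3.05 ± 0.18. 15 of 17 heat shock genes were higher (15 adjusted over the list alone, camera adjusted p = 2.75e-08, adjusted p = 0.0744 with an estimated correlation). HSPH1 was at 2.08 ± 0.23. For endoplasmic reticulum chaperones, 12 of 18 were higher (14 adjusted over the list alone, camera adjusted p = 5.37e-06, adjusted p = 0.129 with an estimated correlation). For the amino acid stress response, 15 of 23 were higher and 1 lower (16 and 2 adjusted over the list alone, camera adjusted p = 3.56e-05, adjusted p = 0.118 with an estimated correlation). CHAC1 was at 3.05 ± 0.21. In DNA replication, 19 of 32 were higher (20 adjusted over the list alone, camera adjusted p = 4.41e-06, adjusted p = 0.432 with an estimated correlation). E2F1 was at 1.69 ± 0.28. 14 of 38 oxidative phosphorylation genes were higher (14 adjusted over the list alone, camera adjusted p = 5.03e-04, adjusted p = 0.341 with an estimated correlation) and 8 of 19 TCA cycle genes were higher (8 adjusted over the list alone, camera adjusted p = 0.00437, adjusted p = 0.0744 with an estimated correlation). CYCS was at 1.54 ± 0.15 and IDH3A at 1.08 ± 0.14. Between HIF1A-null and shNT in hypoxia 6378 genes differed, 3157 higher and 3221 lower, 2306 (867 higher) against 1.5-fold. Library totals gave 2317 higher and 4008 lower (median of all genes -0.12).

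CA9 was lower in shCDK8 than in shNT under hypoxia, at 6.86 ± 0.681 against 50.1 ± 8.38 CPM (-2.87 ± 0.24, adjusted p = 5.55e-07), as were ANKRD37 (-1.91 ± 0.24) and P4HA1 (-1.10 ± 0.17). CA9 was already lower in shCDK8 in normoxia, near the floor, and its response did not differ by edgeR's test. Its gap in hypoxia does not show weaker induction. VEGFA (-0.23 ± 0.14, adjusted p = 0.251), LDHA (-0.19 ± 0.15), PDK1 (-0.30 ± 0.18), EGLN3 (0.02 ± 0.18), SLC2A1 (0.38 ± 0.17) and KDM3A (-0.45 ± 0.18) did not pass the test, although KDM3A did without shNT hypoxia library A (adjusted p = 0.0252). BNIP3 (-0.59 ± 0.16), ADM (-0.63 ± 0.17) and NDRG1 (-0.65 ± 0.24) were lower but lost the call without shNT hypoxia library B or shCDK8 hypoxia library A, and NDRG1 also without shNT hypoxia library A (adjusted p from 0.0681 to 0.396). GRHL3 (6.48 ± 0.60), TM4SF18 (5.48 ± 0.36), TNFSF4 (5.40 ± 0.30), ACTL8 (5.28 ± 0.45), COL17A1 (5.27 ± 0.43) and TGFB2 (5.21 ± 0.35) were highest against shNT. ZNF614 was at least 143-fold lower against the floor, and F10 (-7.71 ± 0.35), CYTH4 (-7.60 ± 0.35), SERPING1 (-6.75 ± 0.56), CYP4F11 (-6.47 ± 0.22) and NFIB (-5.42 ± 0.32) were lower. Of core hypoxia genes, 26 of 51 were lower and 2 higher (28 and 2 adjusted over the list alone, camera adjusted p = 9.92e-06, adjusted p = 0.365 with an estimated correlation). SLC2A3 was at -2.04 ± 0.22. Of DNA replication genes, 19 of 32 were higher (23 adjusted over the list alone, camera adjusted p = 7.32e-07, adjusted p = 0.728 with an estimated correlation). CCNE2 was at 2.16 ± 0.24. Of p53 targets, 11 of 24 were higher and 1 lower (12 and 1 adjusted over the list alone, camera adjusted p = 1.01e-04, adjusted p = 0.333 with an estimated correlation). CDKN1A was at 1.39 ± 0.12. Heat shock genes had 11 of 17 higher (12 adjusted over the list alone, camera adjusted p = 3.16e-05, adjusted p = 0.365 with an estimated correlation). DNAJA1 was at 1.26 ± 0.14. List members called were down to 14 (core hypoxia genes, without shCDK8 hypoxia library A) and 7 (p53 targets, without shCDK8 hypoxia library A). In hypoxia 4325 genes differed between shCDK8 and shNT, 2241 higher and 2084 lower, 1019 (403 higher) against 1.5-fold. The count was 2337 without shNT hypoxia library B, 2195 without shCDK8 hypoxia library A and 2852 without shCDK8 hypoxia library B.

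In shTIP60 under hypoxia 3 of the 12 panel genes differed from shNT. VEGFA was higher (0.63 ± 0.14, adjusted p = 0.00505), a call lost without shTIP60 hypoxia library A (adjusted p = 0.0898), and ANKRD37 was lower (-1.17 ± 0.23). CA9 was at 31.0 ± 2.37 against 50.1 ± 8.38 CPM (-0.69 ± 0.22, adjusted p = 0.0343), lost without shNT hypoxia library A or shTIP60 hypoxia library A or B (adjusted p from 0.116 to 0.202). The other 9 panel genes did not pass the test, at log2 values from -0.19 for BNIP3 to 0.43 for SLC2A1. GJA1 (2795 reads) and TCF21 (1030 reads) had no read in shNT and were at least 843-fold and 311-fold higher against the floor of 3 counts over the group. ITGAD (7.38 ± 0.42) and ALPP, subject to its copy ALPPL2 (7.21 ± 0.43), were higher. ANKRD22 was lower with a ratio of 187 (95% counting interval 51.3 to 1548), and RNF43 (-5.78 ± 0.22), NFIB (-5.41 ± 0.33), DACT1 (-4.85 ± 0.44), SLC1A3 (-4.74 ± 0.32) and GRIN2B (-4.36 ± 0.26) were lower. 24 of 28 mitosis genes were lower (27 adjusted over the list alone, camera adjusted p = 5.54e-10, adjusted p = 0.493 with an estimated correlation). The kinase TTK was at -1.19 ± 0.20 and CENPE at -1.02 ± 0.19. Of interferon-stimulated genes, 16 of 34 were higher (17 adjusted over the list alone, camera adjusted p = 3.68e-04, adjusted p = 0.532 with an estimated correlation). OAS1 was at 4.08 ± 0.73. For NRF2 targets, 9 of 21 were higher and 2 lower (9 and 3 adjusted over the list alone, camera adjusted p = 0.0189, adjusted p = 0.307 with an estimated correlation). HMOX1 was at 2.82 ± 0.15. For angiogenic factors, 6 of 14 were higher and 1 lower (7 and 1 adjusted over the list alone, camera adjusted p = 0.0166, adjusted p = 0.307 with an estimated correlation). Epithelial markers had 7 of 17 higher and 2 lower (7 and 2 adjusted over the list alone, camera adjusted p = 0.0348, adjusted p = 0.572 with an estimated correlation). They included KRT20 (5.31 ± 0.44) and the intestinal mucin MUC2 (4.95 ± 0.52) higher. The list counts here went down to 6 (mitosis, without shNT hypoxia library B), 5 (interferon-stimulated, without shNT hypoxia library B) and 4 (epithelial markers, without shNT hypoxia library B). In hypoxia 3383 genes differed between shTIP60 and shNT, 1755 higher and 1628 lower, 934 (600 higher) against 1.5-fold. Without shNT hypoxia library B the count was 1757, and without shTIP60 hypoxia libraries A or B it was 1709 or 1796.

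The 3 altered lines shared part of their differences from shNT. In normoxia HIF1A-null and shTIP60 had 670 genes called in the same direction (391 higher, 279 lower), where independent lists would share 93.5 and 73.9. HIF1A-null and shCDK8 shared 424 (212 and 212, against 52.8 and 66.1), and shCDK8 and shTIP60 568 (319 and 249, against 92.5 and 91.7). In hypoxia the shared counts were 2064 for HIF1A-null and shCDK8 (1074 and 990, against 456 and 433), 1136 for HIF1A-null and shTIP60 (546 and 590, against 357 and 338) and 1021 for shCDK8 and shTIP60 (521 and 500, against 253 and 219). Calls in opposite directions also exceeded those of independent lists in normoxia for HIF1A-null and shCDK8 (191, 1.61 times) and for shCDK8 and shTIP60 (248, 1.31 times), and were 0.890 times them for HIF1A-null and shTIP60. In hypoxia they were 392 (0.441 times), 358 (0.761 times) and 549 (0.789 times) for the same pairs. Unchanged groups simulated against the same shNT libraries, which hold no true change, shared at most 1 call in 50 draws. The log2 differences of the lines from shNT had covariances across genes of 0.196 to 0.377 (Pearson r 0.229 to 0.437), where the simulated medians were 0.0466 to 0.0514 (0.482 to 0.523), and genes are not independent replicates. The controls were not divided, as each part would hold 1 of the 2 shNT libraries, so part of the excess may come from the shared controls. In the same direction in all 3 lines were 141 higher and 95 lower genes in normoxia and 280 and 280 in hypoxia, where independent lists would give 5.42 and 5.37, and 51.5 and 45.4. CDKN1A was among those higher in all 3 lines in normoxia (0.79 ± 0.12 in HIF1A-null, 1.72 ± 0.12 in shCDK8 and 0.87 ± 0.12 in shTIP60).

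Camera called 139 of 390 tests of the 30 lists over 13 comparisons, 8 of them also with an estimated correlation. By comparison the calls were 14 (shNT), 14 (HIF1A-null), 14 (shCDK8) and 20 (shTIP60) for hypoxia, 9, 4 and 7 for HIF1A-null, shCDK8 and shTIP60 against shNT in normoxia, 15, 6 and 7 in hypoxia, and 14, 11 and 4 for the response differences. Some lists were not called in any comparison. Of 30 Mediator genes, 5 rose and 8 fell with hypoxia in shNT (5 and 9 adjusted over the list alone), and the smallest camera adjusted p over the 13 comparisons was 0.323. Of 18 TIP60 complex genes, 3 rose and 4 fell (3 and 4 adjusted over the list alone, smallest adjusted p = 0.0660), and of 17 Wnt and beta-catenin targets, 4 rose and 5 fell (4 and 6 adjusted over the list alone, smallest adjusted p = 0.155). 3 of 10 carbonic anhydrase and pH genes rose and 2 fell (3 and 2 adjusted over the list alone, smallest adjusted p = 0.226). Blood and endothelial cell markers, a check for other cell types, had 9 testable members, of which edgeR called 0 with hypoxia in shNT (0 at an unadjusted p under 0.05 and 0 by DESeq2; 0 adjusted over the list alone; smallest adjusted p = 0.128 over the 13 comparisons). Against shNT in hypoxia it called 3 of these members in HIF1A-null (1 higher, 2 lower), 2 in shCDK8 (both lower) and 2 in shTIP60 (1 higher, 1 lower), and in each of the other comparisons at most 1. Of the mitochondrially encoded mRNAs, 0 were in the gene table, so that list was not tested.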

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

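The 3 tests on the HIF1A reads of the HIF1A-null line were chosen only after the result was seen. HIF1A reads rose in that line in hypoxia by 1.85 (log2), from 12.6% of the shNT level in normoxia to 74.2% in hypoxia, and the response differed from that of shNT by 2.56 in the test of the difference. The tables argue against cells with intact HIF1A in the HIF1A-null culture, since CA9 stood at 0.510% of the shNT level in hypoxia (0.371 to 0.648% per library) and 48 of the 51 core hypoxia genes lay below the share of HIF1A. What may remain is a transcript of the targeted allele that is retained and more abundant in hypoxia, for which the log2 change of 1.85 is the only value, or reads of the antisense transcript HIF1A-AS2, whose own row gained 0.226 CPM where HIF1A gained 35.3 CPM but would not show antisense reads counted at HIF1A. Without counts per exon and strand these cannot be told apart, and no biological explanation was tested.

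The other results listed here differed between lines, by a test of the difference of the hypoxia responses, and are given as differences of log2 fold changes. HIF1A-null cells differed from shNT at 2553 genes. Among the named genes with a higher response in HIF1A-null were, as log2 differences, HIST1H2BJ 4.16, HIST1H2AC 3.37, HIST2H2BE 3.26, SNORD33 3.41, SNORD77 3.33, HMGCS1 3.65, IDI1 2.61, HSPH1 2.66, HSPA8 2.04, HERPUD1 2.46, HSPA5 2.22, PSAT1 2.34, SESN2 1.88, SLC7A11 1.84, GCLC 1.07, CCNE2 1.67, RFC4 1.33, CDK1 0.95, CDC20 0.94, NIP7 1.12, UTP20 1.08, CYCS 1.48, NDUFS1 0.84, SUCLA2 0.91 and FH 0.85. Named genes with a lower response were CXCR4 -6.55, C4orf47 -4.97, EGLN3 -4.30, FAM13A-AS1 -4.13, MYBPH -3.92, PFKFB4 -3.88, BNIP3 -3.14, PLOD2 -2.89, ANKRD37 -2.69, PPP1R3B -2.33, ENO2 -2.32, SLC2A1 -2.28, GBE1 -1.98, PDK1 -1.98, P4HA1 -1.96, NDRG1 -1.76, KDM3A -1.64 and LDHA -1.32, besides GPR110 at -2.77 or lower, with 0 reads in HIF1A-null hypoxia set to the floor. HIST1H2BJ, HIST2H2BE, MYBPH, FH, CDK1 and CDC20 lost the call without a library. These were shNT normoxia libraries A (FH, CDK1, CDC20) and B (HIST1H2BJ, HIST2H2BE, CDK1), shNT hypoxia libraries A (HIST1H2BJ, MYBPH, CDK1, CDC20) and B (CDC20), HIF1A-null normoxia library B (HIST1H2BJ, CDK1, CDC20), and HIF1A-null hypoxia libraries A (CDC20) and B (HIST1H2BJ, HIST2H2BE, CDK1), with adjusted p from 0.0530 to 0.477. The count was 1179 without shNT normoxia library A, 1640 without HIF1A-null normoxia library B and 1524 without HIF1A-null hypoxia library B.

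The response of shCDK8 differed from that of shNT at 6 genes (532 with the library series as a term), TFRC 1.77, HPCAL1 -1.33, TNFRSF10D -1.64, ANGPTL4 -1.70, HOXA4 -2.06 and DUSP1 -2.23, of which DUSP1 kept its call without each library in turn. The count was 2 without shNT normoxia library A or B, 1 without shCDK8 hypoxia library A and 12 without shNT hypoxia library A. The response of shTIP60 differed at 5 genes, HMOX1 1.37, PAG1 -2.46, SLC2A3 -2.67 and IGFBP3 -3.23, and ZNF608 -1.79, of which IGFBP3 and SLC2A3 kept their calls. That count was 2 without shNT normoxia library B, shTIP60 normoxia library A or shTIP60 hypoxia library B, 3 without shNT normoxia library A, shTIP60 normoxia library B or shTIP60 hypoxia library A, and 10 without shNT hypoxia library A.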

How the results depend on the processing

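The library series as a term, the slopes on genes picked in a series, the list members called without a library and the list without HIF1A were chosen after seeing the data. No call of a named gene or list turned to the opposite direction with a call. Of 9560 alternative values for 704 results of named genes, 9139 kept their side of the threshold, 394 fell short of it and 27 passed it anew; of these, removal of a library gave 193 of the 394 and the test against 1.5-fold 138. Of 834 values for 139 list calls, 650 kept the call and 184 did not. With 1 library removed, the members called in the direction of a list went down by over 1.5 times in 53 of the 139, and to 0 in 10. A removal leaves a group with a lone library, which is assumed to vary like the other groups. The simulated recovery at 2 times was 41.8% for the response difference of HIF1A-null against 85.1% for shNT hypoxia. Except where the construction is named, the cause was not tested.

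The test against 1.5-fold, stricter by construction, gave 1962, 1895, 589 and 1726 genes for hypoxia in shNT, HIF1A-null, shCDK8 and shTIP60, 568, 632 and 835 for HIF1A-null, shCDK8 and shTIP60 against shNT in normoxia, 2306, 1019 and 934 in hypoxia, and 580, 1 and 3 for their response differences. A fit of only the groups compared gave 3442 for HIF1A-null hypoxia, 1026 and 4830 for HIF1A-null and shTIP60 in normoxia, and 1030 and 51 for their response differences. For the response differences of shCDK8 and shTIP60, DESeq2 gave 215 and 59, no filter 384 and 106, and a mean of at least 5 CPM 15 and 10. Thinning gave 11 for shTIP60. Camera with an estimated correlation called 8 of the 390 list tests and fry in its mixed form 309. At a threshold of 0.01, stricter by construction, HIF1A-null and shCDK8, HIF1A-null and shTIP60, and shCDK8 and shTIP60 shared 238, 365 and 282 calls in normoxia and 1056, 573 and 482 in hypoxia. Slopes over genes called up in shNT were 0.448 (HIF1A-null), 0.656 (shCDK8) and 0.783 (shTIP60). Genes picked for their rise in shNT are biased to look weaker elsewhere, so the choice itself can lower these slopes. Over the core hypoxia genes with library totals, the slope of HIF1A-null was 0.382. Over genes picked in the first library series and measured in the second the slopes were 0.475 (HIF1A-null), 0.819 (shCDK8) and 0.886 (shTIP60). In reverse they were 0.571, 0.689 and 0.901.

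No paired analysis was possible because the columns carry no replicate numbers, so the planned replicate block was not fitted, and the library series was fitted as a term in its place. Differences between the library series correlated between groups at 0.0307 to 0.336 (median 0.119; 18 of 28 above 0.1), and 3684 genes differed between the series. With the series as a term, 2959, 3264 and 4287 genes differed in normoxia (HIF1A-null, shCDK8, shTIP60), and 4187, 532 and 72 in the responses; 4 list calls ended, epithelial markers for HIF1A-null in normoxia and shTIP60 in hypoxia, and angiogenic and immediate early genes for the shCDK8 response. Without each library in turn, the counts were 4104 to 5419 (shNT hypoxia), 3937 to 5475 (HIF1A-null hypoxia), 1846 to 3576 (shCDK8 hypoxia), 3786 to 4391 (shTIP60 hypoxia), 1046 to 1563, 1066 to 1814 and 1368 to 1668 (HIF1A-null, shCDK8 and shTIP60 in normoxia), 5027 to 5561, 2195 to 3871 and 1709 to 3074 (in hypoxia) and 1179 to 2985, 1 to 12 and 2 to 10 (responses). The slopes were 0.407 to 0.452, 0.813 to 0.893 and 0.892 to 0.933.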

Other observations

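The test on silent olfactory receptor genes was chosen only after the result was seen, and the genes in the next paragraphs were chosen after their values were seen. 3 histone genes had their highest levels in HIF1A-null cells in hypoxia. HIST1H2AC was at 13.7 and 50.9 CPM in libraries A and B of that group and at most 5.77 CPM in the other 14 libraries, HIST2H2BE at 7.66 and 31.8 CPM against at most 1.73, and HIST1H2BJ at 2.42 and 17.8 CPM against at most 1.12, so that library B held most of these reads.

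In both oxygen conditions, 142 genes differed from shNT in the same direction in all 3 other lines, 79 higher and 63 lower. BMP4, a secreted bone morphogenetic protein, was at 99.6 CPM in shNT in normoxia against 365 in shTIP60, 1374 in shCDK8 and 675 in HIF1A-null, and ABCC2, an organic anion export pump, at 86.8 CPM against 354, 159.7 and 356. Lower in all 3 lines were CSTA, a cysteine protease inhibitor, at 15.5 CPM in shNT in normoxia against 1.69, 1.98 and 2.31, and CAV1, a coat protein of caveolae, at 321 CPM against 163, 189 and 202. EPAS1, which encodes another oxygen-regulated HIF subunit, was at 190.2 CPM in shNT in hypoxia against 92.2 in shTIP60, 70.1 in shCDK8 and 54.2 in HIF1A-null, and its call in HIF1A-null in normoxia ended without shNT normoxia library B (adjusted p = 0.0604).

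The sharing was set against technical explanations. If shNT alone stood apart, more genes would differ from all 3 other lines in shNT than in any other line, but in normoxia the count was 236 for shNT, 0.212 of that for shTIP60 (1114), with 965 for shCDK8 and 627 for HIF1A-null. Chance values of the shared shNT libraries may contribute to the 236. Groups simulated as unchanged from shNT gave at most 0 such genes in 50 draws, but such draws hold no true change, so the planned bound was wrong and decides nothing on genes that did change. No biological explanation was tested.

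The median log2 change in hypoxia over 271 genes with a single exon was -0.14 in shNT, -0.44 in HIF1A-null, -0.07 in shCDK8 and -0.18 in shTIP60, and of these and of 12463 genes with more exons, 38.0% and 19.3% fell in HIF1A-null, 24.4% and 20.9% in shTIP60, 21.4% and 21.1% in shNT, and 9.23% and 11.7% in shCDK8. Expression level, GC content and length do not account for the medians, since at most 1.4% of 10000 sets of genes matched on these had a median as low, over the 4 lines. Olfactory receptor genes were higher in normoxia in 1 of 4 lines, which decides nothing on genomic DNA, since 5 expressed genes held 99.0% of their reads. Genomic DNA is argued against by 0.0818 reads per silent olfactory receptor gene and normoxia library, where the single-exon genes that fell in HIF1A-null lost a median of 329.5 reads. A shift in RNA stability, splicing or polyadenylation may be involved, and none of these was tested.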
